A study of Arabidopsis thaliana with 2 samples.

How the data were processed

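Libraries from total RNA of the main stem of Arabidopsis thaliana, 1 from hdt1 mutant plants and 1 from wild-type plants, were taken from plants grown in long days and collected 35 days after flowering. Genotype and age come from the sample labels. The authors deposited FPKM values (fragments scaled by gene length and by the library's total) for both libraries in a single table with 33669 features, per the file headers and the values. Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1 are named per the submitters' processing notes. The genome build, the annotation, the strand setting and whether reads or read pairs were counted are not given in the sources used here. Of the features 67 carry no locus identifier and were kept out of the comparisons, which left 33602 loci, of which 10166 were at 0 in both libraries. Gene symbols, product descriptions, gene order, transcript length and GC content were taken by locus identifier from the RefSeq annotation of TAIR10.1, in which 32835 loci were found and 767 were not, and no coordinates are given because the build behind the values is not named.

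Depth was read from the values. In FPKM, 1 read is worth a constant divided by gene length, and low values lay on whole multiples of that constant, which gave totals of 21728500 counted in the wild-type library and 23070249 in the hdt1 library. The ratio of the FPKM values then gave a pair of whole read numbers for 21796 features above 0 in both libraries, within a relative error of 1.5e-14. For 1705 features above 0 in 1 library the read number is the smallest that makes the gene length whole, or a multiple of it. The multiple, for these as for the pairs, was settled from the annotated gene length for 90.8% of the 23501 features, and the smallest whole numbers were used for the others, so that their intervals are, if anything, too wide. Reads used in this way sum to 97.3% of the total in the wild-type library and 97.2% in the hdt1 library. With the likeliest multiple taken for every feature they would sum to 102.8% and 102.7%, more than the totals. At these depths 3 reads, the limit that a count of 0 allows, correspond to 0.138 FPKM in the wild-type library and 0.130 FPKM in the hdt1 library for a gene of 1000 bases. Folds carry exact conditional (Clopper-Pearson) intervals at 95% from these reads, and intervals and floors cover counting error only, since reads are not independent molecules.

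With 1 library per genotype no test between genotypes was made, and any interval on the reads compares these 2 libraries and not the genotypes. The log2 ratio of (hdt1 FPKM + 1) to (wild-type FPKM + 1) was computed per gene on the values as deposited, a scale that understates differences of low genes. Genes with a mean of at least 1 FPKM entered, and a gene was counted as higher or lower when the ratio reached 2-fold on that scale. Gene lists (32 lists with 449 entries) were fixed before the data were examined. They cover histone deacetylases, gibberellin, primary and secondary walls, xylem, cambium, phloem, cell division, auxin, wall loosening, photosynthesis, senescence, hormone and stress responses, the clock, flavonoids, glucosinolates, cuticle, ribosome biogenesis, flower and seed markers and reference genes. Members were used by locus, and 6 were left out because the annotation gives their locus another name. Added to these were a family by description (nuclear genes described as ribosomal proteins with no mention of chloroplast, plastid or mitochondria, meant for the cytosolic ones but not checked gene by gene) and by locus (chloroplast and mitochondrial genomes). A list with at least 3 members that entered was described by its median and by the percentile of that median among 10000 random lists of the same size, matched on mean FPKM in 20 bins. Lists of type-A response regulators, class II trehalose phosphate synthases and the KMD family were chosen after the data were seen.

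Genes named in the text follow a rule fixed at the same time as the lists. It takes the HD2 genes, the 12 highest and 12 lowest nuclear log2 ratios among genes with a mean of at least 5 FPKM (without rRNA and tRNA genes), every gene of the gibberellin lists, and of each other list up to 4 members with a mean of at least 1 FPKM and the largest absolute log2 ratio. Genes outside the rule are said to be so where they appear. Of the 194 genes covered by the rule and by the lists chosen later, 41 overlap another gene in the annotation, and reads of overlapping or near-identical genes cannot be assigned with certainty.

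Alternatives set beforehand were pseudocounts of 0.1 and 5, equal FPKM sums, centring on the median of genes with a mean of at least 10 FPKM, equal sums without the 100 most abundant genes and the organelle genes, no filter on low values, a mean of at least 5 FPKM, limits of 1.5-fold and 4-fold, unmatched random lists, and other window sizes. Removal of the trend of log2 ratios with gene length or GC content (the median of 50 bins), the count of genes whose counting interval excludes 1, and a ribosomal description in capital or small letters were added after seeing the data. Intervals of list medians are 95% bootstrap intervals over members with 10000 draws. Members of a list can vary together and are not replicates. These intervals and the percentiles therefore describe these libraries and do not measure variation between plants.

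The steps were tested on simulated data for the hdt1 against wild-type comparison, with Poisson reads drawn from the real means and totals and 200 genes changed, of which 17798 genes in all entered. Genes changed 3-fold were called in the right direction at the 2-fold limit in 94.8% of 97 cases, genes changed 1.5-fold in 0% of 97, and 0.0852% of 17604 unchanged genes were called. Both totals were found, the reads were exact for 99.9% of 21124 genes with a settled factor, and 95.4% of the intervals of 16197 unchanged genes held 1. The simulated genes took the lengths that the same recovery had chosen for the real values. The share of exact reads is therefore no independent check of the multiples chosen there. The simulation has no variation between plants. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.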

Results

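RNA from the main stem of Arabidopsis thaliana was sequenced from hdt1 mutant plants and from wild-type plants, both collected 35 days after flowering. The series holds 1 library per genotype, so no difference between genotypes has a replicate check and no p-value is given. HDT1 encodes one of the plant-specific HD2 histone deacetylases, which are found in the nucleolus and act on chromatin. The deposited FPKM values imply 21728500 counted reads or read pairs in the wild-type library and 23070249 in the hdt1 library. Of 33602 loci, 22524 were above 0 in the wild-type library and 22644 in the hdt1 library, and 17811 had a mean of at least 1 FPKM and entered the comparison. Folds are ratios of the 2 FPKM values, followed in brackets by a 95% exact (Clopper-Pearson) interval that covers counting error in these 2 libraries and nothing else. Log2 ratios and counts of genes past 2-fold are instead on the scale with 1 FPKM added to both values. A low gene can therefore have a fold above 2 without being counted.

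The comparison asks which transcripts differ between the hdt1 and the wild-type stem. HDT1 itself (AT3G44750) was at 5.19 FPKM in the hdt1 library and 52.6 FPKM in the wild-type library, 10.2-fold lower (8.42 to 12.3), from 123 and 1176 reads. It ranked 3 from the lowest log2 ratio among all genes compared. Of 37 genes listed for the cellulose, xylan and lignin of the secondary wall, 34 had a log2 ratio above 0 and 9 were at least 2-fold higher in the hdt1 library. Of 19 jasmonate genes 17 were above 0, 8 were at least 2-fold higher and 1 was 2-fold lower. The kelch-repeat gene KMD1 (AT1G80440) was higher, and of the gibberellin 2-oxidases GA2OX2 was 3.34-fold lower while GA2OX8 and GA2OX6 were 2.78-fold and 2.58-fold higher. Of 222 genes described as ribosomal proteins without mention of an organelle 211 were below 0, none of them by 2-fold with 1 FPKM added.

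The other HD2 genes were lower by small amounts. HDT4 was 1.43-fold lower (1.17 to 1.74), HDT3 1.29-fold (1.18 to 1.41) and HDT2 1.22-fold (1.16 to 1.27). A gene on the opposite strand, AT3G44740, overlaps HDT1 in the annotation. It was at 9.66 FPKM in the wild-type library and 4.60 in the hdt1 library, and whether the counting used strand is not given in the sources used here. Of the 10 other histone deacetylase genes that entered, none was 2-fold higher or lower. HDA2 was 1.31-fold lower (1.16 to 1.47) and HDA19 1.12-fold higher (1.06 to 1.19), and the list median was -0.03 on the log2 scale, a value that was above 0 under each of the 3 other scalings.

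At least 2-fold differences on the log2(FPKM + 1) scale were found for 545 genes, 413 higher and 132 lower in the hdt1 library, and 17266 genes lay between. The counting interval of the fold lay above 1 for 403 of the 413 and below 1 for 126 of the 132. Genes were ranked among nuclear genes with a mean of at least 5 FPKM, without rRNA and tRNA genes. The highest log2 ratio among them, 4.1, belonged to AT3G44006, an uncharacterized gene. It was at 0.256 FPKM in the wild-type library and 20.5 in the hdt1 library. Its wild-type value rests on as little as 1 read, and the ratio of 80.1 has an interval from 14.0 to 3199. AT1G02610, a RING/FYVE/PHD zinc finger gene, was 14.5-fold higher (12.2 to 17.3). TPS8, of the trehalose phosphate synthase family, was at 13.4 FPKM in the wild-type library and 163 in the hdt1 library, 12.2-fold higher (11.4 to 13.0). KMD1, a kelch-repeat F-box gene whose family acts in the turnover of type-B cytokinin response regulators, was 8.21-fold higher (7.81 to 8.65). CYP94B1, an enzyme that oxidises jasmonoyl-isoleucine, was 9.97-fold higher (7.86 to 12.8), and MAF5, a MADS-box relative of the floral repressor FLC, 9.25-fold higher (6.80 to 12.9). RD26, a NAC factor induced by drought and abscisate, was 7.2-fold higher (6.23 to 8.36), RAV2 7.23-fold and the stress gene OXS3 6.96-fold. AT2G24550 was 7.36-fold higher, the glycosyl hydrolase gene AT4G18340 8.38-fold and the AP2-type factor AT4G28140 6.84-fold.

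At the other end, AT3G01345, an uncharacterized gene, was at 34.0 FPKM in the wild-type library and 0.134 in the hdt1 library, 253-fold lower (108 to 780). RTFL7, a small peptide of the ROTUNDIFOLIA-like family, was 10.8-fold lower from at least 214 and 21 reads, close to the difference of HDT1. DR4, a gene repressed by drought, was 6.11-fold lower (5.56 to 6.74). ARR6, a type-A response regulator induced by cytokinin, was at 95.2 and 21.1 FPKM, 4.5-fold lower (4.07 to 4.99). The calmodulin-like gene CML41 was 4.85-fold lower, and the ERF factors RAP2.6 and Rap2.6L 4.36-fold and 4.14-fold lower. The defensin PDF1.2b was 4.88-fold lower (3.27 to 7.51), AT1G77145 5.56-fold and AT3G30122 5.45-fold. The snoRNA gene AT2G35742 rests on 22 and 5 reads, 4.67-fold lower (1.73 to 15.8).

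**Figure D1:**
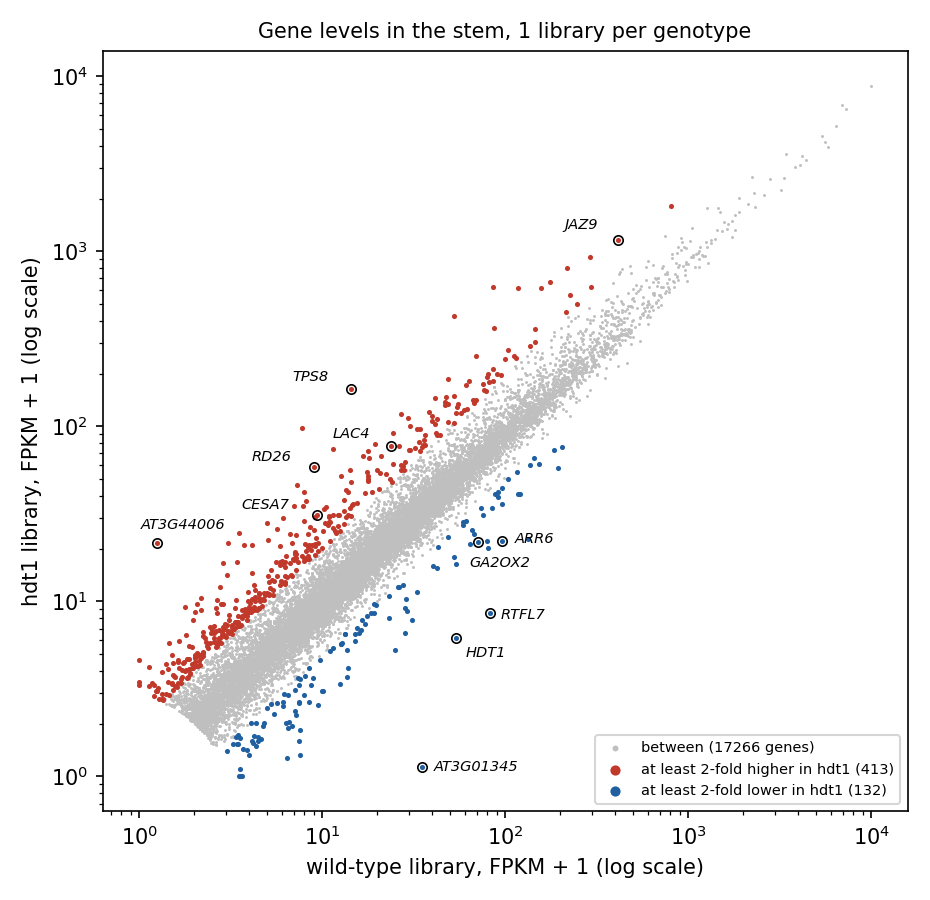
FPKM + 1 of the 17811 genes with a mean of at least 1 FPKM in the wild-type library (x axis) and in the hdt1 library (y axis), both on log scales, with 1 point per gene and 1 library per genotype. Red points are the 413 genes at least 2-fold higher in the hdt1 library, blue points the 132 genes at least 2-fold lower, and circles mark genes named in the text, among them HDT1 at 52.6 and 5.19 FPKM.

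Gibberellin drives stem elongation, and 3 lists of its genes were examined. The 2-oxidases, which inactivate gibberellin, went both ways. GA2OX2 was at 69.9 FPKM in the wild-type library and 20.9 in the hdt1 library, 3.34-fold lower (3.06 to 3.66), whereas GA2OX8 was 2.78-fold higher (1.95 to 4.05) and GA2OX6 2.58-fold higher (1.95 to 3.45). Their median log2 ratio of 1.08 rests on these 3 genes and was 0.13 with no filter on low values. GA2OX1, GA2OX3, GA2OX4 and GA2OX7 had at most 4 reads in a library. Of the 5 biosynthesis genes that entered, each was between the 2-fold limits and below 0, with a median of -0.11 at percentile 23.4 of 10000 random lists matched on mean FPKM. GA20OX1, which catalyses the late steps that limit gibberellin supply in the stem, was 1.73-fold lower (1.28 to 2.35) and KAO1 1.26-fold lower (1.1 to 1.44). GA2, GA3 and KAO2 had intervals that include 1. GA20OX2 was at 0.690 and 0.898 FPKM, and GA3OX1 at 0.586 and 0.173 FPKM from 16 and 5 reads. GA1 had 4 and 6 reads, GA20OX3 had 3 and 0, GA3OX2 had 1 and 0, GA3OX4 had 1 in either library, and GA20OX4, GA20OX5 and GA3OX3 were listed at 0 in both. In the signalling list 7 of 13 members were above 0 and 6 below, with a median of 0.03 at percentile 76.1. The receptor gene GID1B was 2.18-fold lower (1.85 to 2.57) and GID1A 1.19-fold lower, and GID1C was 1.09-fold higher (1.01 to 1.19). Among the DELLA repressors RGL3 was 2.26-fold higher (1.81 to 2.83) and RGL2 1.73-fold lower (1.25 to 2.43), and GAI, RGA1 and RGL1 had intervals that include 1. The F-box gene SLY1 was 1.38-fold lower (1.25 to 1.53). Of the gibberellin-responsive GASA genes, GASA4 was 2.53-fold higher (1.77 to 3.66) and GASA14 1.41-fold higher (1.29 to 1.55), while GASA1 and GASA6 had intervals that include 1.

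Most genes of the secondary wall had higher values in the hdt1 library. Of the 5 secondary wall cellulose genes, 4 were at least 2-fold higher and the median log2 ratio was 1.23, at percentile 99.99 of the matched random lists. The cellulose synthases CESA7, CESA4 and CESA8, which work together in xylem and fibre walls, were 3.59-fold (3.28 to 3.93), 2.65-fold (2.43 to 2.90) and 2.55-fold (2.30 to 2.84) higher, and the chitinase-like gene CTL2 2.28-fold higher. Of 12 xylan genes 10 were above 0 and 1 was 2-fold higher with 1 FPKM added, and the median was 0.54 at percentile 100. GUX1 was 2.26-fold higher (1.92 to 2.67), IRX9 2.36-fold, TBL29 2.08-fold and GAUT12 2.03-fold, while the xylan genes IRX9-L and IRX14-L, named after their values were seen, had log2 ratios of -0.24 and -0.32. Of 20 lignin genes 19 were above 0 and 4 were 2-fold higher, with a median of 0.49 at percentile 100. CCR2 was 4.07-fold higher (3.42 to 4.87), the laccase LAC4 3.36-fold (3.13 to 3.61), and PAL1 and PAL2, which open the phenylpropanoid pathway, 2.46-fold and 2.19-fold. The lowest log2 ratios of the lignin list were those of CAD5 (-0.01), HCT (0.19) and CCR1 (0.23), named after their values were seen. Among 22 transcription factors of the secondary wall, MYB52 and MYB63 were at least 2-fold higher with 1 FPKM added and none was 2-fold lower. Of the 22, 16 were above 0 and 6 below, and the median was 0.25 at percentile 99.9. The counting interval lay above 1 for 9 of them and below 1 for 2, VNI2 and MYB4, named after their values were seen, with log2 ratios of -0.86 and -0.75. The list was not divided into activators and repressors, so its median gives no direction of control. MYB63 was 2.66-fold higher (2.0 to 3.57), MYB52 2.39-fold, VND3 2.76-fold (1.81 to 4.33) and NST3, a master switch of fibre walls, 1.97-fold (1.68 to 2.31). The primary wall cellulose genes were above 0 in 10 of 10 cases, with a median of 0.52 at percentile 100. The lowest median under the alternatives run was 0.36, and the random lists were not matched on gene length. None was counted as 2-fold higher with 1 FPKM added. KOR1 was 1.60-fold higher, CESA5 1.62-fold, CSI1 1.59-fold and CESA9 2.05-fold from 72 and 157 reads.

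Markers of other stem tissues stood beside these wall genes as follows. The 4 phloem genes were above 0, with a median of 0.35 at percentile 97.8 of matched and 96.8 of unmatched lists. SEOR1, a protein of sieve elements, was 2.1-fold higher (1.90 to 2.33), the sucrose carrier SUC2 1.33-fold, APL 1.25-fold and PP2-A1 1.18-fold. Of 18 cambium genes 13 were above 0 and 1 was 2-fold higher with 1 FPKM added, and the median was 0.38 at percentile 100. TMO6 was 2.49-fold higher (1.93 to 3.22), the D-type cyclin CYCD3;1 2.2-fold, HB-8 1.84-fold and HCA2 2.01-fold from at least 15 and 32 reads. The 5 genes of xylem cell death went both ways, with a median of 0.01 at percentile 46.3 that was below 0 under 2 of the settings tried. XCP2 and XCP1, cysteine proteases of xylem vessels, were 2.09-fold and 2.39-fold higher, whereas the metacaspase MC9 was 3.38-fold lower (2.39 to 4.85) and the RNase RNS3 2.31-fold lower (1.52 to 3.58). Most cell division genes had low FPKM values, and 6 of 13 entered. Their median was 0.59 at percentile 99.6, with a bootstrap interval over members from -0.02 to 0.89, which includes 0. Only HIS4, at -0.10, was below 0. The members that did not enter were above 0. They were CYCA1;1 (0.82), PCNA1 (0.64), CDKB1;1 (0.60), CYCB1;4 (0.48), MCM2 (0.26), AUR1 (0.21) and CYCB1;1 (0.12). Of these, the counting interval includes 1 for AUR1 and CYCB1;1 and lies above 1 for the rest. These genes and HIS4 were named after their values were seen. With no filter on low values the median was also 0.59. The cytokinesis syntaxin KN was 2.33-fold higher (1.58 to 3.49), CDKB2;2 2.17-fold, CDKB2;1 1.77-fold and CYCB1;2 3.77-fold (1.02 to 20.8) from as little as 3 and 12 reads. In the auxin list 8 of 10 members were above 0 and 1 was 2-fold higher, with a median of 0.46 at percentile 99.96. IAA19, an early auxin response gene, was 2.83-fold higher (2.22 to 3.62), DFL1 1.65-fold, PIN7 1.53-fold and AUX1 1.48-fold. Of 16 wall loosening genes 12 were above 0 and 3 were 2-fold higher, with a median of 0.29 at percentile 99.97. The expansins EXPA4 and EXPA6 were 2.51-fold and 2.19-fold higher, XTH9 1.97-fold and XTH15 8.01-fold (1.90 to 71.4) from as little as 2 and 17 reads. Cuticle and epidermis genes had a median of -0.09 at percentile 21.7, with none of 16 past 2-fold with 1 FPKM added. LTP2 and LTP1 were 2.02-fold and 1.78-fold higher, and the wax and cuticle genes KCS1 and CER2 1.86-fold and 1.54-fold lower. Of the flower organ markers 3 of 10 entered, with a median of -0.04 that was above 0 under 2 of the 3 other scalings, and SHP1 was at 21.1 and 20.5 FPKM, SEP1 at 1.94 and 1.47, and SEP3 at 0.907 and 1.63. None of the 9 seed markers reached a mean of 1 FPKM.

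**Figure D2:**
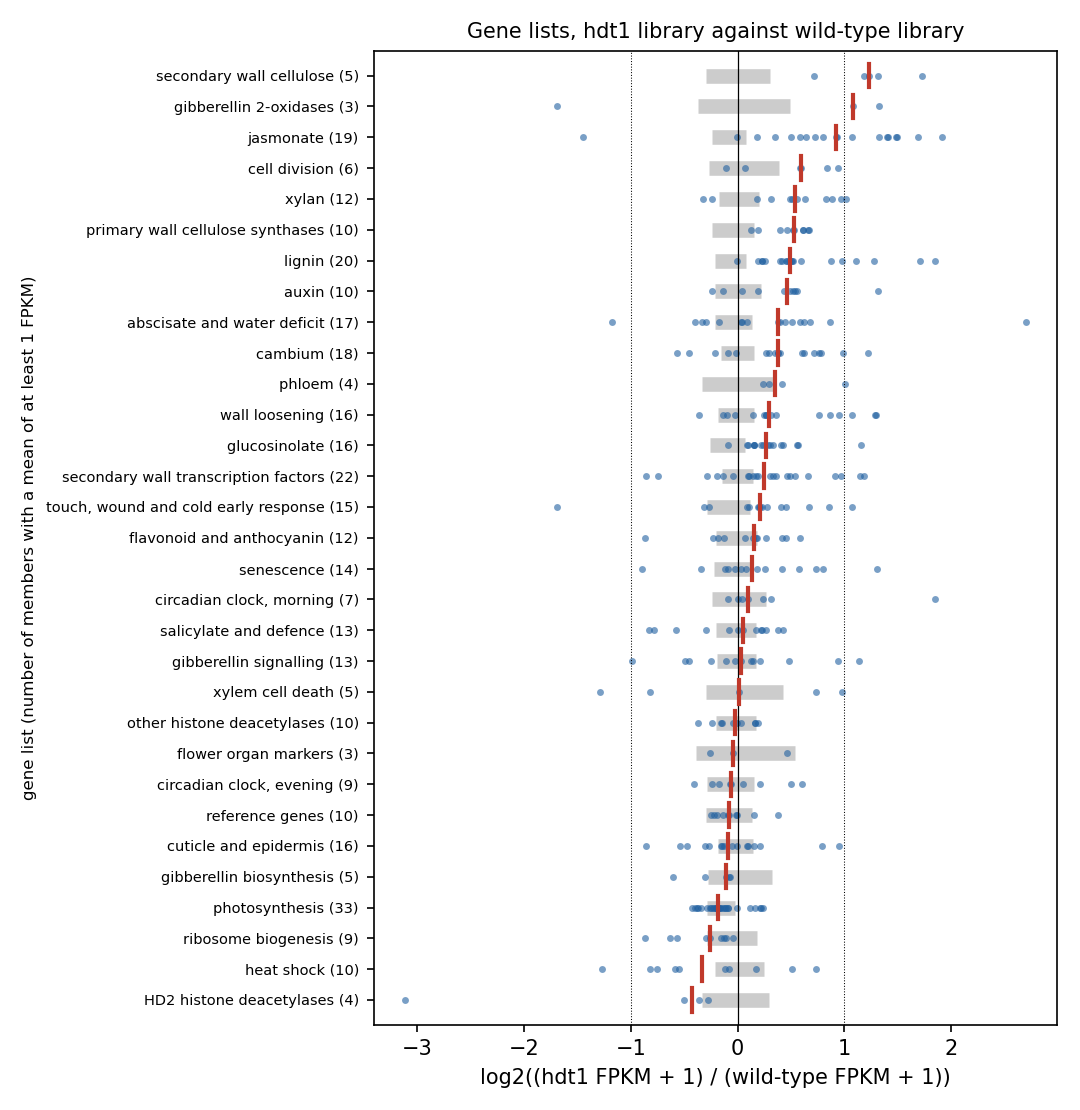
Log2 ratios of hdt1 over wild-type FPKM, each with 1 added, on the x axis for the 31 gene lists fixed beforehand that had at least 3 members with a mean of at least 1 FPKM. Blue points are single genes, red bars list medians, and grey bands the central 95% of the medians of 10000 matched random lists; the secondary wall cellulose median of 1.23 and the jasmonate median of 0.92 lie to the right of their bands, and dotted lines mark 2-fold.

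Jasmonate genes also had mostly higher values in the hdt1 library. Of 19 members 17 were above 0, 8 were at least 2-fold higher and 1 was 2-fold lower, with a median of 0.92 at percentile 100. The repressors JAZ8, JAZ7 and JAZ9 were 3.89-fold (3.41 to 4.44), 3.34-fold (2.93 to 3.81) and 2.81-fold (2.75 to 2.88) higher, and LOX3, a lipoxygenase of jasmonate synthesis, 2.89-fold (2.71 to 3.09). VSP1, the member that was 2-fold lower and was named after its value was seen, had a log2 ratio of -1.45. Early touch, wound and cold genes, which mark handling of the tissue, were above 0 in 12 of 15 cases with a median of 0.21 at percentile 99.7. RRTF1 was 2.13-fold higher (1.99 to 2.28), ERF104 1.81-fold and WRKY40 1.60-fold, and CBF3 was 5.02-fold lower (3.27 to 7.99). Genes of abscisate and water deficit had a median of 0.38 at percentile 100, with 12 of 17 above 0 and a bootstrap interval from -0.17 to 0.59, which includes 0. That median was 0.16 with a pseudocount of 5 and 0.11 with no filter on low values. Besides RD26, KIN1 was 3.23-fold higher (1.35 to 8.87) from 7 and 24 reads and RAB18 1.61-fold higher, while KIN2 was 2.28-fold lower (2.0 to 2.61). The salicylate and defence list had a median of 0.05 at percentile 81.9 and none of 13 past 2-fold. The pathogenesis-related genes PR5 and BGL2 were 1.80-fold and 1.75-fold lower, WAK1 was 1.5-fold lower, and the interval of NIMIN1 includes 1. Heat shock genes had a median of -0.33 at percentile 0.13, with 7 of 10 below 0 and a bootstrap interval from -0.75 to 0.21, which includes 0. HSFA2, a heat stress factor, was 2.65-fold lower (1.66 to 4.36), HSP101 1.84-fold and HSP70 1.78-fold lower, and HSP17.6A 2.96-fold higher (1.22 to 8.20) from 7 and 22 reads.

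Glucosinolate genes were above 0 in 15 of 16 cases with a median of 0.26 at percentile 99.97. CYP79B3, which makes the precursor of indole glucosinolates, was 2.30-fold higher (1.82 to 2.92), MYB29 1.5-fold, CYP83B1 1.48-fold and CYP79B2 1.36-fold. Flavonoid and anthocyanin genes had a median of 0.16 at percentile 95.9, with none of 12 past 2-fold. PAP2 was 1.84-fold lower (1.70 to 1.98), CHI was 1.63-fold higher, TT8 1.62-fold and DFR 1.38-fold. The senescence list had a median of 0.13 at percentile 98.5 of matched lists and 95.3 of unmatched lists, inside the central 95% of the latter. Of its members 9 of 14 were above 0, and the bootstrap interval from -0.07 to 0.57 includes 0. WRKY6 was 2.79-fold higher (2.37 to 3.29), NAP 1.80-fold and WRKY75 1.70-fold, while SAG12, the classical marker of leaf senescence, was 1.88-fold lower (1.75 to 2.02).

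Most genes for ribosomal proteins had lower values in the hdt1 library. These 222 genes are a set taken by description that can also hold ribosomal proteins of organelles and other proteins. Of them 211 were below 0 and none was 2-fold lower with 1 FPKM added. The median was -0.36 at percentile 0, or 1.28-fold lower on that scale. The quartiles were -0.46 and -0.23, the range was -0.68 to 0.36, and the counting interval lay below 1 for 188 of the 222. AT2G19740 was at 233 FPKM in the wild-type library and 148 in the hdt1 library, 1.58-fold lower (1.49 to 1.67), and AT3G12915, an elongation factor gene, was 1.77-fold lower. AT2G07696, of the S7p/S5e family, and AT3G09680 were 2.32-fold and 2.41-fold lower from 35 and 16 reads and from 25 and 11 reads. The 9 ribosome biogenesis genes were below 0, with a median of -0.26 at percentile 5.05 of matched lists, inside their central 95%, and 1.43 of unmatched lists, outside it. The nucleolins and fibrillarins, proteins of the nucleolus, included NUC2 at 2.09-fold lower (1.71 to 2.56), FIB2 at 1.57-fold and FIB1 at 1.23-fold, and AT5G27120 was 1.49-fold lower. Photosynthesis genes were below 0 in 28 of 33 cases, with none 2-fold lower and a median of -0.18, which lay at percentile 40.4, as 95% of the matched random lists had medians from -0.28 to -0.02. Against unmatched lists it lay at percentile 0.385, outside the central 95%, and with the length trend removed, a setting added after seeing the data, the median was -0.06. LHCB2.2 was 1.34-fold lower, PSBR 1.32-fold, and PSBQ-2 and PSAE-1 1.3-fold. Genes of the chloroplast genome held 1.63% of the FPKM sum in the wild-type library and 1.59% in the hdt1 library, so their summed share did not rise. Their median was 0.20 at percentile 100, and the counting interval lay above 1 for 19 of 86 and below 1 for 8. At least 2-fold higher were 7 of the 86. Of these ATCG00410 rests on at least 8 and 26 reads and ATCG00560 on 7 and 20, and the intervals of ATCG00260 and ATCG00320 include 1. Genes of the mitochondrial genome had a median of -0.13 at percentile 0.37, with none of 47 past 2-fold with 1 FPKM added. ATMG01120, ATMG01220, ATMG00040 and ATMG00140 had log2 ratios from -0.89 to -0.81, from few reads. ATMG00140 rests on as little as 3 and 1 reads, and its interval includes 1. ATMG01120 rests on at least 19 and 8 reads and ATMG00040 on at least 21 and 8.

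Clock genes went both ways, and the counting interval excluded 1 for 10 of 16. The morning list had a median of 0.10 at percentile 79.3 and the evening list a median of -0.06 at percentile 60.9, which was above 0 under 1 of the 3 other scalings. RVE1 was 7.61-fold higher (5.05 to 11.9) from 26 and 210 reads, CCA1 1.26-fold, LNK2 1.18-fold, PRR5 1.54-fold and TOC1 1.42-fold higher, FKF1 was 1.33-fold and BOA 1.19-fold lower, and the interval of LNK1 includes 1. Reference genes had a median of -0.08 at percentile 60.3, with UBQ10 1.3-fold higher and YLS8, GAPC1 and ACT8 1.19-fold, 1.16-fold and 1.14-fold lower.

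Genes next to HDT1 in locus order differed about as often as genes elsewhere. Among the 50 genes on either side of HDT1 in locus order, 4 of 100 differed at least 2-fold, 3 higher and 1 lower. One of them is AT3G44006, which had the highest log2 ratio of the genes named by rank and lies 43 genes from HDT1. The others, named after their values were seen, are FAMT at a distance of 4 genes with a log2 ratio of 1.5, AT3G45160 at 21 genes with 1.02, and AT3G44450 at 17 genes with -1.07. In 173 other windows of that size the median was 3, the range was 0 to 9, and 62 windows held at least as many. No nuclear gene was listed at 0 in one library and at 5 FPKM or more in the other.

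The number of genes past 2-fold depended on the constant added before the logarithm, with 652 higher and 246 lower at 0.1 FPKM and 167 higher and 47 lower at 5 FPKM. Log2 ratios were also higher for longer genes, with a Spearman rho of 0.29 across 17811 genes, which are not independent replicates, and the wall, jasmonate and ribosomal medians kept their sign after that trend was removed.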

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

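The features without a locus identifier lie outside the comparisons of the report. Of 67 such features 48 had a mean of at least 1 FPKM, 1 was at least 2-fold higher in the hdt1 library and 0 were 2-fold lower. That feature was at 3.02 FPKM in the hdt1 library and 0.554 in the wild-type library, a ratio of 5.44 (2.66 to 12.6, counting error only).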

How the results depend on the processing

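Length and GC corrections, the count restricted by the counting interval and the ribosomal description in any letters were chosen after the data were seen. No paired analysis was possible because each genotype has 1 library, and for the same reason no library could be left out. Genes at least 2-fold higher numbered 652 with a pseudocount of 0.1, 167 with 5, 271 with a mean of at least 5 FPKM, 1254 at 1.5-fold and 37 at 4-fold, against 413. Genes lower numbered 246, 47, 79, 572 and 11 in the same order, against 132. Stricter limits and filters leave fewer genes by construction, and a larger pseudocount shrinks the ratios of low genes. The log2 ratio of HDT1 was -2.50 with a pseudocount of 5, against -3.12. The gibberellin 2-oxidase median was 0.13 with no filter, against 1.08, since members with few reads then enter. Against unmatched random lists the percentile was 96.8 for phloem, 0.385 for photosynthesis, 95.3 for senescence and 1.43 for ribosome biogenesis, and the cause was not tested. Nuclear genes at 0 in one library numbered 20 when 1 FPKM in the other sufficed, against 0. Of 328 alternative list medians 327 moved by less than 1.5-fold, 33 of 37 lists did not change the sign of their median under the alternatives run, and the 4 others had medians of at most 0.06 in size. Of 950 alternative log2 ratios of named genes 917 moved by less than 1.5-fold and none of at least 1.5-fold changed sign. Scalings moved the median of all genes from -0.03 to at most 0.03. Depth limits genes with few reads, such as CYCB1;2 and XTH15.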

Other observations

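The tests on vascular tissue, time of day and handling were chosen only after the results were seen, as were the gene families in the next paragraph, each of which holds a gene that prompted its choice and is given as values and not as a test.

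Type-A response regulators, which cytokinin induces, were mostly lower in the hdt1 library. Of 8 that entered 7 were below 0 and 5 were at least 2-fold lower, with a median log2 ratio of -1.19, or -1.17 without ARR6, which prompted the choice. ARR6 was 4.5-fold lower, ARR16 4.36-fold (2.88 to 6.78), ARR5 3.14-fold (2.87 to 3.44), ARR15 2.36-fold and ARR7 2.35-fold, ARR4 and ARR8 were 1.64-fold and 1.48-fold lower, and ARR9 was 1.66-fold higher (1.47 to 1.88). The KMD family, F-box proteins that act in the turnover of the type-B regulators which drive these genes, went the other way, with log2 ratios above 0 for the 3 members that entered, 2 of them besides KMD1, which prompted the choice. KMD1 was 8.21-fold higher, KMD4 was at 37.3 and 120 FPKM, 3.22-fold higher (3.02 to 3.43), KMD2 was 1.65-fold higher, and KMD3 was listed at 0 in both libraries. Among the class II trehalose phosphate synthases, many of which respond to sugar supply, 2 of 7 were at least 2-fold higher, TPS8 at 12.2-fold and TPS11 at 2.68-fold (2.44 to 2.95), and the family median was 0.27, or 0.25 without TPS8, which prompted the choice.

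Most secondary wall genes had higher values in the hdt1 library, with a pooled median of 0.52 over 37 cellulose, xylan and lignin genes. After the trend with gene length was removed the median was 0.570 (0.521 to 0.839), and after the trend with GC content 0.545 (0.497 to 0.885), so neither trend accounts for it. A larger share of vascular tissue in the hdt1 sample remains possible. The 4 phloem genes were higher too, and the secondary wall median exceeded theirs by 0.169, with an interval from -0.480 to 0.518. The phloem list is short and that interval wide, so its including 0 cannot decide. Cellulose genes alone had a median of 1.23, xylan genes 0.54 and lignin genes 0.49, against 0.35 for phloem. The phloem list also lay inside the range of unmatched random lists at percentile 96.8, and the xylem cell death genes went both ways. An effect of the hdt1 genotype on wall genes remains open, and 1 library per genotype cannot part it from differences between the plants sampled.

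Most genes described as ribosomal proteins without mention of an organelle had lower values in the hdt1 library, with a median of -0.36 over 222 genes. Their transcripts are short, with a median length of 855 bases against 1494 for all genes, and short genes were lower in the hdt1 library. Removal of the length trend brought the median to -0.205 (-0.221 to -0.189), so length may account for part of it. Removal of the GC trend left it at -0.324 (-0.343 to -0.300). Random lists matched on mean FPKM also had medians below 0, in a central range from -0.152 to -0.059. Length and abundance were not removed together, so whether they jointly account for the whole difference was not tested. An effect of the hdt1 mutation on these genes was not tested beyond this and remains open. HDT1 is a nucleolar protein, whose level was not measured here.

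Most jasmonate genes had higher values in the hdt1 library, with a median of 0.92 over 19 genes. The length trend does not account for it, since the median without that trend was 0.987 (0.644 to 1.43). For a different time of day at harvest, the median absolute log2 ratio of 16 clock genes was 0.193 (0.068 to 0.320) against 0.93 for the jasmonate genes. That met the outcome set against it. The test replaced the difference between the morning and evening medians (0.16, -0.27 to 0.48) once the evening genes were seen to go both ways. It assumes that a time shift moves both sets by as much, which was not shown, so it cannot decide. Time of day remains open, since the counting interval excluded 1 for 10 of the 16. RVE1 (1.85), PRR5 (0.60) and TOC1 (0.50) had higher log2 ratios. For wounding or handling at harvest, the early touch, wound and cold genes had a median of 0.213 (0.110 to 0.454), above most matched random lists at percentile 99.7. The upper end of that interval stayed below the jasmonate median of 0.92. The outcomes set for and against handling were both met, so this test cannot decide. Handling may contribute, and an effect of the genotype remains open beside it.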
